A study of Rattus norvegicus with 6 samples.

How the data were processed

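RNA was measured in 6 samples of differentiated Rcho-1 trophoblast stem cells, 3 with control shRNA and 3 labelled Fosl1 shRNA. Per the labels' protocols, the cells were transduced with lentivirus and differentiated for 8 days, RNA was extracted with Trizol, and biotinylated cRNA was hybridised to an Affymetrix rat array that reads each transcript by sets of short probes (probe sets). The authors deposited 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes, MAS5 and Affymetrix Expression Console were used; their versions, the scaling settings and the genome build are not given in the sources used here. In the deposited values, each array's mean over its probe sets, with 2% trimmed at either end, was close to 500, so the arrays already share a scale. MAS5 signals of dim probe sets are mostly noise, and a scaling to a common mean hides any change in total RNA per cell. Detection calls were not used here, and no other sample columns were present.

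Probe sets were named from the platform annotation: of 31099 probe sets, 20832 had 1 gene symbol, 436 had several and 9831 had none, or 9780 without the controls. Of all probe sets, 57 were Affymetrix controls. Gene identifiers of 20764 probe sets were found in the rat gene table, which changed 0 symbols. The platform annotation can be old. Names came only from probe sets with 1 symbol, and no coordinates are given because no genome build is named.

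Signals under 1 were set to 1 and log2 transformed. Controls were left out, and so were probe sets whose mean log2 signal lay under the 40th percentile, a signal of about 56.8, which left 18625 probe sets. Of these, 14054 had 1 symbol and stood for 10240 genes. Each gene was represented by its tested probe set with the highest mean log2 signal. Of the 140 called genes with several tested probe sets, 107 had all of them on the same side. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with group as the only term, a two-sided test and Benjamini-Hochberg adjustment over all tested probe sets. A difference was called at an adjusted p under 0.05. SDs are over signals of the 3 samples of a group, and folds are from the fitted mean log2 signals. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Pairs of arrays of the same group differed with an SD of 0.45 to 0.53 on the log2 scale, and 0 pairs were identical. No depth can be counted on an array.

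Of 25 fixed gene lists, the 23 with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 23. The 25 lists were the AP-1 and Grainyhead-like families, matrix proteases and inhibitors, placental prolactins, placental cathepsins, trophoblast stem state, trophoblast differentiation, steroidogenesis, cholesterol synthesis, mitosis, DNA replication, cyclin-dependent kinase control, angiogenic factors, cytokines, adhesion and matrix, epithelial and mesenchymal state, interferon response, p53 and apoptosis, stress, iron and nutrient handling, and markers of fibroblasts, endothelium, leukocytes, visceral endoderm and erythroid cells. Camera called 4 of the 23 and 0 with an estimated correlation, where the lowest adjusted p of any list was 0.602. With 4 residual degrees of freedom the estimated version had little room to call a list. An adjusted p of 0.602 there does not speak against a single list. The groups, the test, the filter, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the AP-1 and Grainyhead-like genes, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose higher group mean was at or above the median of all probe sets, and up to 4 members of each list with the smallest p. Loci without a proper symbol were passed over. The further called members of the prolactin, protease and adhesion lists (Prl2b1, Prl8a2, Adamts4, Lamc1 and Itga7) and the bright members Prl7a3, Prl2a1 and Fn1 were named after their values were seen.

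Array-level measures (median signal, upper end of the signals, 3-prime to 5-prime ratios and spiked-in controls) were compared by an exact permutation test, two-sided, whose smallest p with 3 against 3 is 0.1. The procedure was tested on simulated data for the labelled Fosl1 against control comparison, with 200 of 18625 probe sets changed. It recovered 10% of the changes of 1.5-fold, 38% of those of 2-fold, 80% of those of 3-fold and 78% of those of 4-fold, with 1 false call among 104, 0 calls when nothing was changed, and the 1 shifted list found. The simulated probe sets varied independently of one another, whereas the cholesterol list had an estimated correlation of 0.58. The simulation therefore does not measure false calls among lists whose members vary together. The alternatives were quantile normalization, centring each array on its median, an offset of 16 on the signals, no filter and a 60th percentile filter, eBayes without the trend, array weights, the mean of a gene's probe sets, the replicate number as a block, camera with an estimated correlation, fry, and leaving out each of the 6 samples. Figures were drawn with matplotlib 3.10.9.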

Results

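Total RNA was profiled on 6 Affymetrix rat expression arrays from Rcho-1 trophoblast stem cells, a rat choriocarcinoma line whose cells can be kept as stem cells or made to differentiate into trophoblast giant cells, the large invasive and hormone-secreting cells of the rodent placenta. All cells had been differentiated for 8 days after lentiviral delivery of a short hairpin RNA (shRNA). The labels put 3 samples in the control shRNA group and 3 in the Fosl1 shRNA group. Every array held 31099 probe sets, with a median signal of 99.95, 102.1 and 107.5 on the control arrays and 108.3, 109.4 and 104.9 on the arrays labelled Fosl1 shRNA. Signals of the tested probe sets correlated at r = 0.966 to 0.975 in the 6 pairs of arrays of the same group and at r = 0.951 to 0.967 in the 9 pairs of arrays of different groups. On the first principal component control replicates 1, 2 and 3 lay at -44.1, -25.0 and -7.60, and the labelled Fosl1 replicates at 30.6, 34.0 and 12.1. The labelled Fosl1 replicate 3 stood apart on the second principal component, at -44.7 where the other 5 arrays lay between 1.64 and 16.99. The number of arrays limits the precision of every value below.

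The comparison asks which transcripts differ in differentiated trophoblast cells when Fosl1 is knocked down. Fosl1 encodes an AP-1 transcription factor that pairs with Jun proteins. Its signal was 6692, 5787 and 5170 in control replicates 1, 2 and 3, and 4519, 4366 and 4966 in the labelled Fosl1 replicates 1, 2 and 3. The group means were 5883 ± 765 (SD, n = 3) and 4617 ± 312 (SD, n = 3), a log2 difference of -0.34 with a standard error of 0.12. All 3 labelled Fosl1 signals lay below all 3 control signals. The labelled Fosl1 arrays held 78.8% of the control level, with a 95% confidence interval of 66.1% to 93.9%, and limma's adjusted p was 0.121, or 0.0269 with array weights. Of the 10240 genes tested, 1207 had a larger fall than Fosl1. The other AP-1 genes did not pass the test either: 0 of the 15 tested family members were called over all genes by limma, where 405 of the 10240 genes were, and 0 when adjusted over the list alone. At an unadjusted limma p under 0.05 stood 2350 of the 10240 genes. In the family these were Fosl1, Maf, Atf3 and Jdp2, at 0.0120, 0.0135, 0.0210 and 0.0273. Fos stood at a log2 difference of -0.15, Jun at -0.07, Junb at -0.18, Fosl2 at -0.11 and Atf3 at 0.34, with adjusted p of 0.540, 0.756, 0.606, 0.749 and 0.159 in limma. The largest differences of the family were those of Maf, at 1.02, and Jdp2, at -0.47, with limma adjusted p of 0.128 and 0.178, and 12 of the 15 had lower values. Camera gave the AP-1 family an adjusted p of 0.319, or an adjusted p = 0.621 with an estimated correlation.

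A different transcription factor gene was strongly lower in the same arrays. Grhl1, a Grainyhead-like factor of epithelial cells, had signals of 1324, 941 and 1076 in the control samples and of 171, 191 and 67.1 in the labelled Fosl1 samples. Its mean fell from 1114 ± 195 to 143 ± 66.5 (SD, n = 3 each), 8.49-fold, with a log2 difference of -3.09, a standard error of 0.32 and a limma adjusted p of 0.00101, or 0.0709 without the intensity trend. No other gene had a larger fall by its brightest probe set. A second Grhl1 probe set went from 469 ± 145 to 100 ± 26.2, 4.64-fold lower, with an adjusted p of 0.00294 in limma. Grhl3 differed by a log2 value of -0.18 with an adjusted p of 0.687 in limma, and adjusting over the Grainyhead-like list alone left Grhl1 as the 1 of 2 tested members that fell. Grhl2 was not analysed here. The array descriptions of the 3 samples labelled Fosl1 shRNA begin with the letters Grhl and a running number, while their other labels name Fosl1 shRNA. Fosl1 was thus lower without being called while Grhl1 fell strongly, and every direction below is stated for the arrays labelled Fosl1 shRNA and not for a verified loss of Fosl1.

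**Figure D1:**
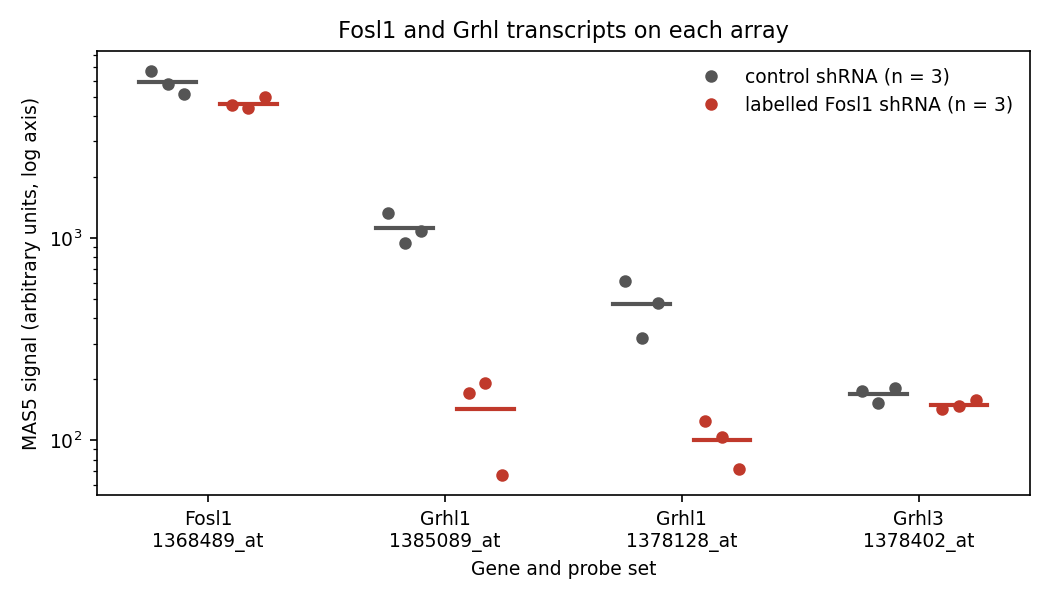
MAS5 signal on a log axis for Fosl1, Grhl1 by both its probe sets, and Grhl3, with 1 point per array, 3 control arrays and 3 arrays labelled Fosl1 shRNA, and a line at each group mean. Fosl1 means were 5883 and 4617, while Grhl1 went from 1114 to 143 and from 469 to 100, and all 3 labelled Fosl1 arrays lay below all 3 control arrays for Fosl1 and for both Grhl1 probe sets.

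Limma called 659 of 18625 tested probe sets at an adjusted p under 0.05, of which 354 were higher and 305 lower than in the controls. The balance depended on the scaling, since 318 of 652 called probe sets were higher with each array centred on its median. They stood for 405 of 10240 genes, 233 higher and 172 lower, with a median fold of 1.61. A difference of at least 2-fold was found for 78 of them, 57 higher and 21 lower. The labelled Fosl1 and control values did not overlap for 2713 genes, or 26.5%, where chance gives 10%. The number of calls depended on single samples: it was 200, 48 and 773 genes without control replicates 1, 2 and 3, and 52, 49 and 510 genes without the labelled Fosl1 replicates 1, 2 and 3. Whichever sample was left out, 38 of the 405 genes were called each time.

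Fam236d had the largest rise among called genes, from 59.8 ± 36.8 to 318 ± 45.4 (SD, n = 3), with a log2 difference of 2.70 and a limma adjusted p of 0.0168. Hsd11b2, which inactivates glucocorticoids, rose from 34.9 ± 21.2 to 163 ± 33.7, a log2 difference of 2.49. Mmp19, a matrix metalloproteinase, rose from 32.1 ± 18.7 to 132 ± 34.5, a log2 difference of 2.25. Laptm5, a lysosomal membrane protein best known in leukocytes, rose 4.49-fold from 67.0 ± 5.0 to 305 ± 67.7, and Cd55, an inhibitor of complement, rose 3.28-fold from 152 ± 8.44 to 501 ± 68.8. The actin-cytoskeleton gene Zfp185 rose 3.98-fold, and Taf7l, a relative of a TFIID subunit, rose 2.99-fold from 297 ± 46.9 to 884 ± 90.6. The other genes among the 12 largest rises were Alox5ap, which rose 3.01-fold, and Or13p4, Kcnq5, Sertad4 and Lalba, which rose from control means of 36.0, 41.4, 48.7 and 47.6 to 140, 133, 155 and 140. These 4 genes, Hsd11b2 and Mmp19 had control means under the filter level of 56.8, where signals are mostly noise, so their folds are imprecise. The same holds for Fam236d, with control signals of 82.6, 17.3 and 79.5 around that level. Cd55, Taf7l, Laptm5 and Zfp185 had limma adjusted p of 0.00101, 0.001002, 0.00237 and 0.00389 and stayed called whichever sample was left out. Mmp19, Hsd11b2, Or13p4 and Fam236d had limma adjusted p of 0.0444, 0.0310, 0.0445 and 0.0168, and of 0.193, 0.143, 0.208 and 0.0830 without the labelled Fosl1 replicates 1, 2, 2 and 2, respectively. Alox5ap and Lalba were at 0.105 and 0.135 without the labelled Fosl1 replicate 1, Sertad4 at 0.132 without the labelled Fosl1 replicate 2 and Kcnq5 at 0.156 without control replicate 2. The log2 difference of Fam236d was 1.96 and that of Hsd11b2 1.78 without control replicate 2 (limma adjusted p 0.0145 and 0.0662), and that of Mmp19 was 1.62 without control replicate 1 (0.0750).

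Among the falls after Grhl1, Crb3, an apical polarity protein, fell 3.17-fold from 291 ± 32.6 to 91.7 ± 1.5 (SD, n = 3), with a limma adjusted p of 0.00329. Its other 2 probe sets were called lower as well, 1 of them by a log2 difference of -3.40. Spint2, an inhibitor of membrane-bound serine proteases, was 2.76-fold lower, at 508 ± 31.6 against 195 ± 86.7. Elf5, a transcription factor of trophoblast stem cells, fell 2.22-fold from 533 ± 237 to 227 ± 27.6. Chdh, the choline dehydrogenase of mitochondria, was 2.85-fold lower, and Cyb5r3, a cytochrome b5 reductase, went from 2036 ± 448 to 843 ± 142, 2.40-fold lower. Cmklr2, Mfap5 and Ankrd37 were 3.79-, 2.69- and 2.36-fold lower, and Rsph6a fell from 126 to a labelled Fosl1 mean of 30.2, under the filter level. The pseudogene symbols Nid2-ps16 and Syncrip-ps2 completed the 12 largest falls at 2.62- and 2.20-fold. Such probe sets can also detect related transcripts, so these names are uncertain. Crb3 and Cyb5r3 stayed called whichever sample was left out, while Spint2 and Elf5 had limma adjusted p of 0.0123 and 0.0318 and reached 0.0657 without control replicate 2 and 0.129 without the labelled Fosl1 replicate 1. Chdh and Cmklr2 were at 0.0654 and 0.105 without the labelled Fosl1 replicate 1, and Mfap5, Rsph6a, Ankrd37 and Syncrip-ps2 at 0.109, 0.130, 0.0581 and 0.0673 without control replicate 2. Without control replicate 1 the log2 differences of Cmklr2, Elf5 and Chdh shrank from -1.92, -1.15 and -1.51 to -1.39, -0.81 and -1.18. Their limma adjusted p was then 0.0615, 0.0662 and 0.0182.

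**Figure D2:**
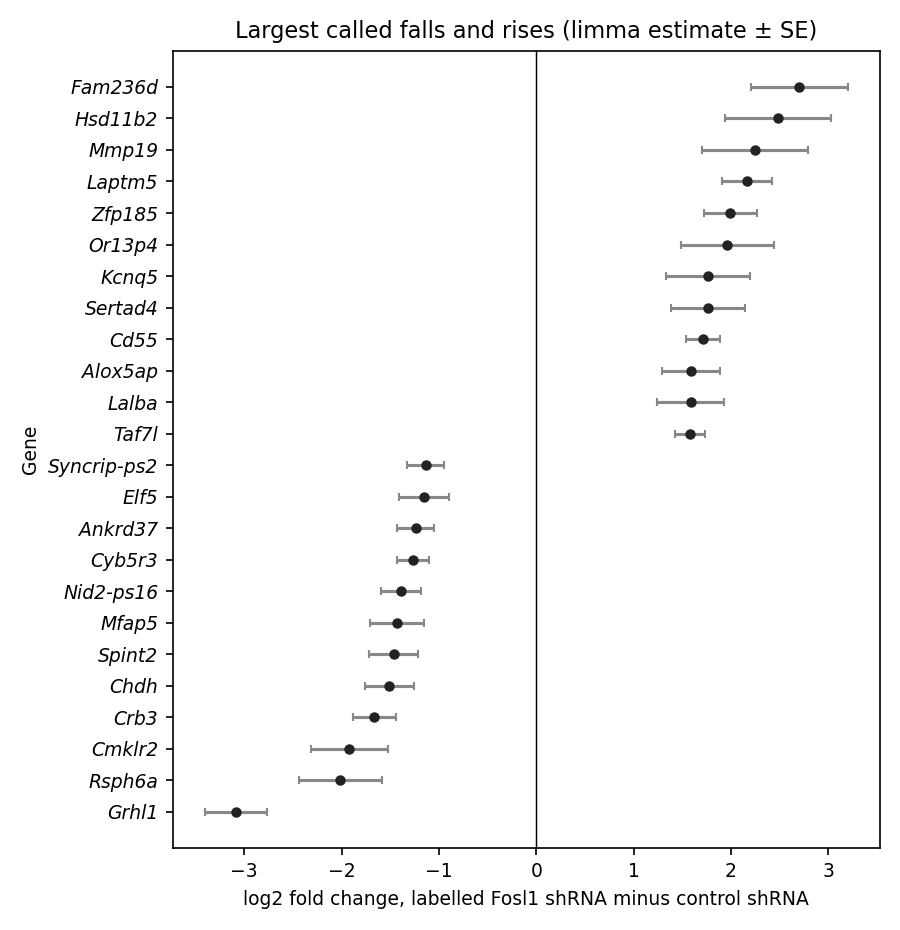
Log2 fold change of the labelled Fosl1 arrays minus the control arrays for the 12 largest called rises and 12 largest called falls, 3 arrays per group, with bars of 1 standard error on each side. The falls end at -3.09 for Grhl1, and the rises at 2.70 for Fam236d.

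Placental hormone genes of the prolactin family moved in both directions. Of 14 tested members, 5 rose, 1 fell and 8 did not pass, and adjusted over the list alone 5 rose and 3 fell. Prl3b1, placental lactogen II, rose 2.55-fold from 6890 ± 593 to 17511 ± 905 (SD, n = 3), with a limma adjusted p of 0.000374, and stayed called whichever sample was left out. Prl7d1 and Prl2b1 rose 2.32- and 2.62-fold from low levels of 101 ± 18.3 and 70.6 ± 25.4, and Prl8a2 and Prl6a1 rose 1.58- and 1.49-fold. Prl8a7 fell 1.92-fold from 4225 ± 695 to 2222 ± 513. The limma adjusted p of Prl7d1 and Prl8a7 was 0.0216 and 0.0120, and 0.0911 and 0.0730 without the labelled Fosl1 replicate 2. Prl6a1 was at 0.133 without that replicate, and Prl2b1 and Prl8a2 at 0.150 and 0.144 without the labelled Fosl1 replicate 1, so that Prl3b1 was the 1 of the 5 rises called in every such run. The brightest members, Prl7a3 and Prl2a1, stood at 51441 ± 10399 and 44232 ± 7194 in the controls and had log2 differences of 0.40 and 0.42, with adjusted p of 0.316 and 0.273 in limma. The list as a whole did not pass, with a camera adjusted p of 0.338, or an adjusted p = 0.746 with an estimated correlation, and 0.0290 by camera without the labelled Fosl1 replicate 1. These genes are close paralogs, so a probe set can detect more than its named gene. Of the placental cathepsins, 1 was tested, Ctsq, at a log2 difference of 0.45 and a limma adjusted p of 0.395.

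Stem-state and differentiation genes showed few changes. Of 17 stem-state genes 0 rose and 2 fell, Elf5 and Esrrb, the second by 2.05-fold from 215 ± 22.8 to 106 ± 24.5 (SD, n = 3). The counts were 2 up and 2 down when adjusted over the list alone. Cdx2, a trophectoderm factor, had a log2 difference of 0.42 and Fgfr2 of 0.45, with limma adjusted p of 0.0626 and 0.0984 over all genes. The other tested Fgfr2 probe set went the other way, and the log2 difference of Fgfr2 ranged from 0.20 to 0.59 over the alternatives. Among 25 differentiation genes, H19 rose 1.46-fold, Ceacam3 fell 1.59-fold from 16666 ± 1395 to 10497 ± 1094, and Bhlhe40 fell 1.63-fold, and 4 rose and 2 fell when adjusted over the list alone. Camera gave adjusted p of 0.990 for the stem-state list and 0.476 for the differentiation list. Esrrb and H19 had limma adjusted p of 0.0439 and 0.0391, which became 0.152 without the labelled Fosl1 replicate 2 and 0.136 without control replicate 2. Bhlhe40 was at 0.198 without the labelled Fosl1 replicate 2 and Ceacam3 at 0.0947 without control replicate 2.

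Called matrix-remodelling and adhesion genes were mostly higher in the labelled Fosl1 arrays, at 5 of 22 and 6 of 28 tested, and both lists had a camera adjusted p of 0.0180 but an adjusted p = 0.602 with an estimated correlation. Of 22 proteases and inhibitors, 5 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell. The risers held inhibitors as well as proteases: Serpine2, an inhibitor of plasminogen activators and thrombin, rose 2.05-fold from 626 ± 35.3 to 1292 ± 168 (SD, n = 3), Timp2, an inhibitor of metalloproteinases, rose 2.03-fold, and the proteases Adamts4 and Adam19 rose 2.05- and 1.60-fold beside Mmp19. Mmp9, the gelatinase of invading trophoblast cells, fell 1.70-fold from 6248 ± 1228 to 3650 ± 530. Of 28 adhesion and extracellular matrix genes, 6 rose and 0 fell in limma, and adjusted over the list alone 7 rose and 0 fell. Col5a1, a fibrillar collagen chain, rose 2.36-fold, Itga6, a laminin receptor subunit, rose 1.75-fold from 2557 ± 377 to 4458 ± 286 by its brightest probe set, with 1 of its 3 others at a log2 difference of -0.04, and Itga7, Lamc1, Nid2 and Itgav rose 1.63-, 1.59-, 1.59- and 1.35-fold. Fn1, the brightest member at 18536 ± 760 in the controls, had a limma adjusted p of 0.999. Without the labelled Fosl1 replicate 3 the camera adjusted p of these 2 lists was 0.141 and 0.0698, and 0.0566 for both without the intensity trend. The limma call of Serpine2 held whichever sample was left out, while those of Timp2, Mmp19, Adam19, Adamts4 and Mmp9 were lost, at adjusted p of 0.111 and 0.193 without the labelled Fosl1 replicate 1, 0.0891 without control replicate 2, and 0.128 and 0.110 without the labelled Fosl1 replicate 2. None of the 6 adhesion calls held in every such run: the highest limma adjusted p was 0.0512, 0.173 and 0.167 for Itga6, Itga7 and Itgav without control replicate 2, and 0.0763, 0.108 and 0.178 for Col5a1, Nid2 and Lamc1 without the labelled Fosl1 replicate 2.

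Of 17 cholesterol synthesis genes, 2 rose and 15 did not pass the test, and the list had a camera adjusted p of 0.000163 but an adjusted p = 0.602 with an estimated correlation. Of the 17, 16 had higher mean log2 signals in the labelled Fosl1 arrays, with a median log2 difference of 0.38. Mvk, mevalonate kinase, rose 1.86-fold from 275 ± 38.3 to 515 ± 103 (SD, n = 3), and Sqle, squalene epoxidase, rose 1.66-fold from 2297 ± 639 to 3708 ± 344. None of the 17 fell in limma, and adjusted over the list alone 6 rose and 0 fell. Dhcr7 and Lss had log2 differences of 0.49 and 0.45 with limma adjusted p of 0.0832 and 0.0585. In steroidogenesis, Hsd11b2 rose and Cyp17a1, the enzyme that makes androgens, fell 1.45-fold from 4300 ± 313 to 2973 ± 235, among 11 tested genes. In that list 4 rose and 1 fell when adjusted over the list alone, and the camera adjusted p was 0.375. Scarb1, the receptor that takes up lipoprotein cholesterol, had a log2 difference of 0.62 and a limma adjusted p of 0.0551. The limma adjusted p of Mvk and Sqle was 0.0242 and 0.0434, and 0.117 and 0.133 without the labelled Fosl1 replicate 1, where Cyp17a1 was at 0.0963. Without control replicate 1 the log2 difference of Sqle shrank from 0.73 to 0.49 (limma adjusted p 0.0635). The median of the cholesterol list ranged from 0.17 to 0.43 over 15 alternatives. At the preset correlation camera called the list in all 15.

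Interferon-response genes had higher values without any single call. Of 20 tested, 18 had higher mean log2 signals, with a median log2 difference of 0.34, and limma called 0, also when adjusted over the list alone. Isg15 had the smallest p, at 216 ± 100 against 497 ± 140 (SD, n = 3) and a limma adjusted p of 0.0621. Cxcl10, Irf7 and Psmb9 had log2 differences of 0.92, 0.82 and 0.55, with limma adjusted p of 0.0857, 0.113 and 0.171. The camera adjusted p was 0.0180, and its adjusted p = 0.602 with an estimated correlation. Camera put the list at 0.0610 without control replicate 2, at 0.0745 without the labelled Fosl1 replicate 2, at 0.309 without the filter on dim probe sets and at 0.0503 with the 60th percentile filter.

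Angiogenic, growth-factor and growth-control genes gave a few rises. Epas1, the hypoxia-inducible factor 2 alpha gene, rose 2.21-fold from 559 ± 24.1 to 1238 ± 133 (SD, n = 3), with a limma adjusted p of 0.00119. Nppb, a natriuretic peptide, and Mdk, the growth factor midkine, rose 2.22- and 1.51-fold. These were the 3 of 19 angiogenic and vasoactive genes that rose, and 0 fell in limma. Adjusted over the list alone 4 rose and 0 fell, with a camera adjusted p of 0.0621, or an adjusted p = 0.602 with an estimated correlation. The camera value was 0.0269 without control replicate 2, 0.0350 without the labelled Fosl1 replicate 1, 0.0490 with median centring, 0.0197 with the 60th percentile filter and 0.0263 with the mean of a gene's probe sets. Of 18 cytokines and growth factors, Tgfb3 and Hbegf rose 1.77- and 1.92-fold and 0 fell in limma, the same counts when adjusted over the list alone, with a camera adjusted p of 0.375. Ccnd3, cyclin D3, rose 2.17-fold from 1078 ± 128 to 2349 ± 363 as the 1 of 20 cyclin-dependent kinase control genes called. With values adjusted over the list alone 1 rose and 2 fell, and the camera adjusted p was 0.246. Myc and Mycn had log2 differences of -0.64 and -0.63, with limma adjusted p of 0.0719 and 0.0676. Igfbp3, an insulin-like growth factor binding protein, rose 1.89-fold from 1548 ± 127 to 2925 ± 48.8 as the 1 of 23 iron, nutrient and glycogen genes called, while Slc3a2, Fabp5 and Slc27a1 had log2 differences of -0.56, -0.43 and -0.37 with limma adjusted p of 0.0720, 0.0678 and 0.0897. Here 4 rose and 3 fell when adjusted over the list alone, with a camera adjusted p of 0.915. Epas1, Ccnd3 and Igfbp3 stayed called whichever sample was left out, while Nppb and Hbegf, at limma adjusted p of 0.0190 and 0.0478, were at 0.0963 and 0.182 without the labelled Fosl1 replicate 1. Without the intensity trend Epas1, Ccnd3 and Igfbp3 were not called, at limma adjusted p of 0.0687, 0.0844 and 0.0709. Tgfb3 was at 0.102 without control replicate 2 and Mdk at 0.107 without the labelled Fosl1 replicate 2.

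Cell-cycle and stress genes were mostly not called. Of 29 mitotic genes limma called 0, also when adjusted over the list alone, and the 4 with the smallest p went both ways: Kif23, Cks2, Racgap1 and Bub1 had log2 differences of 0.76, 0.34, -0.26 and -0.37 with limma adjusted p of 0.164, 0.149, 0.152 and 0.173. Lig1, DNA ligase I, fell 1.53-fold from 928 ± 30.3 to 606 ± 54.8 (SD, n = 3) as the 1 of 33 DNA replication genes called, and 1 rose and 1 fell when adjusted over the list alone. The camera adjusted p was 0.915 for both lists, and for DNA replication the median and mean log2 differences, 0.03 and 0.01, lay above 0 while camera's direction was down. In the stress list, Ddit3, a transcription factor of the unfolded protein response, fell 2.02-fold from 3613 ± 1878 to 1652 ± 130, and Dnajb1, a heat shock co-chaperone, rose 1.48-fold by its brighter probe set, among 22 genes. The other tested Dnajb1 probe set went the other way without a call, and the mean of both had a log2 difference of 0.24 and a limma adjusted p of 0.258. The stress list had 1 up and 4 down when adjusted over the list alone, with a camera adjusted p of 0.0624, or an adjusted p = 0.602 with an estimated correlation. The camera value was 0.0428 with quantile normalization, 0.0324 with the replicate block, and 0.0269, 0.0471 and 0.0472 without control replicate 2, control replicate 3 and the labelled Fosl1 replicate 2. Mcl1, which blocks apoptosis, fell 1.43-fold as the 1 of 17 p53 and apoptosis genes called, over all genes and adjusted over the list alone, with a camera adjusted p of 0.338. Of 24 epithelial and mesenchymal genes limma called 0, also when adjusted over the list alone, with a camera adjusted p of 0.990. The 4 with the smallest p, Snai1, Tpm2, Ocln and Cldn7, had log2 differences of -0.50, 0.44, -0.55 and -0.38 and limma adjusted p of 0.0967, 0.0989, 0.0993 and 0.105. The other probe set of Tpm2 was called higher, and that of Ocln stood at a log2 difference of 0.08. The median and mean of that list, 0.08 and 0.04, lay above 0 while camera's direction was down. Ddit3 and Mcl1, at limma adjusted p of 0.0496 and 0.0380, were at 0.149 and 0.196 without the labelled Fosl1 replicates 1 and 2. Without control replicate 1 the log2 difference of Ddit3 shrank from -1.01 to -0.61 (limma adjusted p 0.0352). Lig1 was at 0.110 without the labelled Fosl1 replicate 2, and Dnajb1 at 0.172 without control replicate 2.

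**Figure D3:**
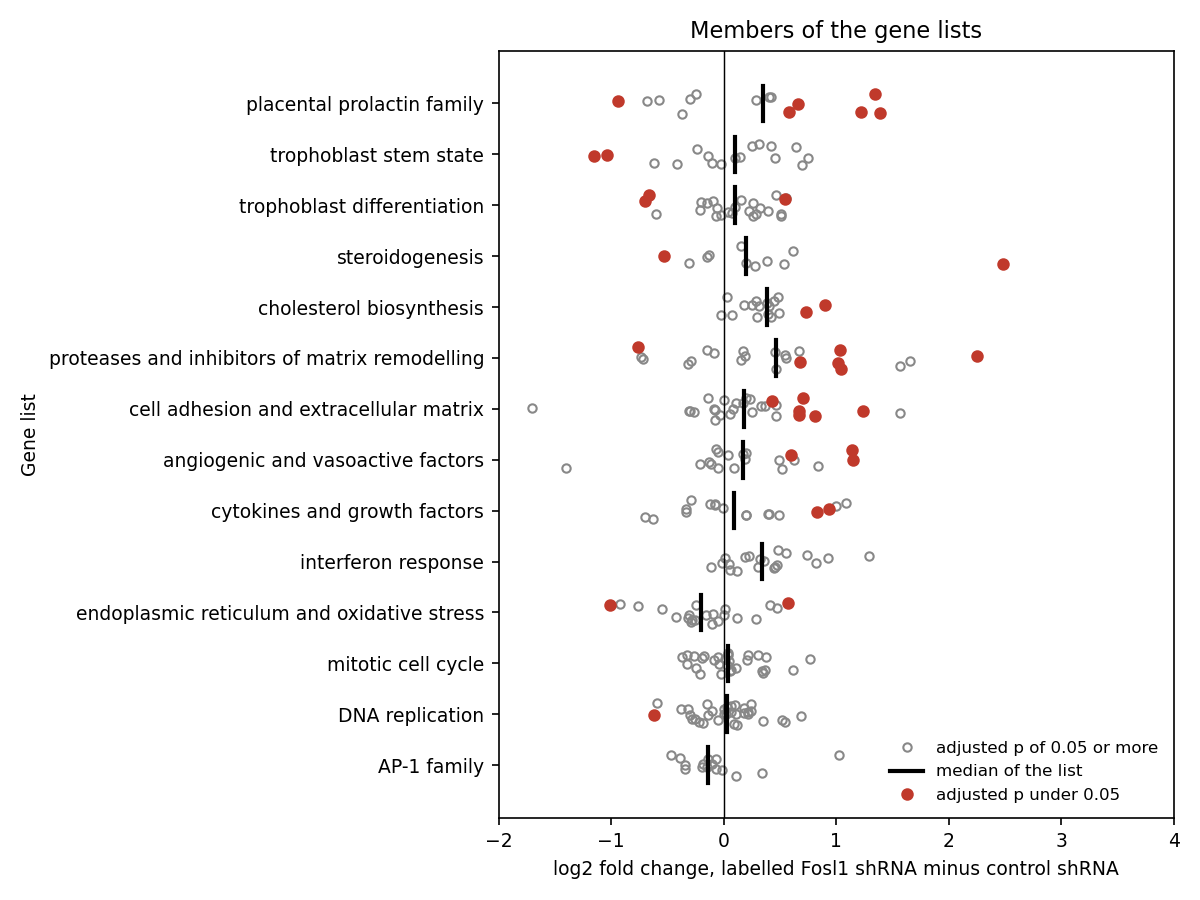
Log2 fold change of each tested member of 14 gene lists, labelled Fosl1 arrays minus control arrays, 3 arrays per group, with filled points for limma adjusted p under 0.05, open points for the others and a black line at each list's median. In the cholesterol synthesis list 16 of 17 points lie to the right of 0, with a median of 0.38, and the prolactin list holds called members on both sides.

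Markers of other cell types gave single calls. Laptm5 was the 1 of 5 tested leukocyte markers that rose, over all genes and adjusted over the list alone, with a camera adjusted p of 0.246; Csf1r, Lyz2 and Fcer1g had limma adjusted p of 0.249, 0.711 and 0.719. Mfap5, a microfibril protein, was the 1 of 6 fibroblast markers that fell, from 539 ± 156 to 203 ± 79.4 (SD, n = 3), while Pdgfrb and Col3a1 had log2 differences of 1.27 and 0.69 and limma adjusted p of 0.0932 and 0.391. Adjusted over the list alone 1 rose and 1 fell. Limma called 0 of 3 endothelial, 0 of 5 visceral endoderm and 0 of 3 erythroid markers. Adjusted over the list alone, 1 visceral endoderm marker, Amn, rose and 1, Apoa4, fell, and 0 endothelial and 0 erythroid markers were called. The other tested Amn probe set went the other way, and the log2 difference of Amn, 0.80, ranged from 0.29 to 0.91 over the alternatives. The camera adjusted p was 0.915 for the fibroblast, endothelial and visceral endoderm lists and 0.803 for the erythroid list. RNA quality was measured by the ratio of the 3-prime to the 5-prime actin probe sets. Its log2 value was 2.20 ± 0.06 in the controls and 2.18 ± 0.34 in the labelled Fosl1 arrays (SD, n = 3). The exact permutation p was 1. On a linear scale the ratio was 4.63, 4.39 and 4.74 in control replicates 1, 2 and 3. In the labelled Fosl1 arrays it ran from 3.48 in replicate 1 to 5.39 in replicate 2. The GAPDH ratio lay between 0.994 and 1.06 on all arrays, with an exact permutation p of 0.3. Actin and GAPDH thus gave different pictures, and 3 arrays per group cannot show that RNA quality was equal.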

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

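The tests of a wrong label, of a Fosl1 transcript lowered at least 2-fold and of scanner saturation, and the counts of probe sets, genes and genes of at least 2-fold over other splits, were chosen after the result was seen.

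The P1 cre hybridization control, which is spiked in and is not part of the comparison, had a higher mean on the arrays labelled Fosl1 shRNA. The log2 difference was 0.385, with signals of 36810, 42331 and 49930 on the control arrays and 40615, 64998 and 65599 on the labelled Fosl1 arrays, and an exact permutation p of 0.3 (0.6 after adjustment over 8 array measures).

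The first pattern is that Grhl1 was strongly lower in the arrays labelled Fosl1 shRNA, while Fosl1, at 78.8% of control, was lower without being called. Saturation of the scanner at the Fosl1 level is argued against by Prl3b1, which rose by 1.35 on the log2 scale from a control signal above that of Fosl1. Whether the Fosl1 probe set itself is saturated could not be decided. Of the 905 tested probe sets at least as bright, 0 were called with a fall of 1 or more on the log2 scale, where 2.72 were to be expected. That count cannot decide, because falls of other probe sets do not show whether the Fosl1 probes are saturated. A Fosl1 transcript lowered at least 2-fold stays open with it. The lower end of the 95% interval of Fosl1, -0.60, is short of a 2-fold fall. The interval holds only for a probe set that is not saturated. A wrong label, with Grhl1 knocked down in these cells, may account for the pattern and stays open: that both Grhl1 probe sets were among the 8 largest falls of 18625 restates the pattern and tests nothing, so only the letters Grhl in the array descriptions speak for it. Lower activity of either factor stays open, including lower FOSL1 protein with little change in its transcript and Grhl1 as a gene that falls after it: of 30 epithelial Grainyhead-like targets Spint2 was the 1 called, lower, with a camera p of 0.175, direction down, and of 29 AP-1 targets 1 rose and 1 fell, with a camera p of 0.471, direction up.

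The second pattern is that Prl3b1 was higher on the arrays labelled Fosl1 shRNA, where the highest signals of replicates 2 and 3, 78824 and 80108, exceeded those of the other 4 arrays. A stretch of the bright end on single arrays is argued against by its log2 difference of 1.29 after quantile normalization, which gives all arrays the same distribution. The biological difference named by the labels stays open and untested beyond the comparison itself.

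With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The labelled split gave 659 probe sets, 405 genes and 78 genes of at least 2-fold, where the highest of the other splits gave 0, so that 1 of the 10 splits reached each count. At an unadjusted limma p under 0.05 the labelled split gave 3881 probe sets. The split of control replicates 1 and 2 with the labelled Fosl1 replicate 3 against the other arrays gave 2327, where chance gives about 931. The other splits mix the groups, so a group difference adds to their spread and lowers their counts. The labelled split gave 4 gene lists, where the highest other split gave 6, and 2 of the 10 splits gave as many.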

How the results depend on the processing

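All settings here were fixed in advance. The number of calls depended on how the spread was estimated. Without the intensity trend limma called 8 probe sets, 4 genes, 4 of at least 2-fold and 2 lists, and Grhl1 kept its log2 difference of -3.09 with an adjusted p of 0.0709. Limma's prior degrees of freedom, which measure how much it borrows from other probe sets, were 8.25 with the trend and 2.65 without it. The residual ones were 4. Most calls thus depended on the spread borrowed with the trend. Array weights gave 2693 probe sets, 1651 genes and 180 of at least 2-fold, and Fosl1 was called at -0.35 with an adjusted p of 0.0269 (range over its alternatives 0.0269 to 0.352); the cause was not tested. Testing more probe sets without the filter gave 359 probe sets and 219 genes. Camera with an estimated correlation and directional fry each called 0 lists and mixed fry 17; camera's preset correlation called 4. With the replicate number as a block limma called 110 probe sets, 65 genes and 38 of at least 2-fold. No sign of pairing by number was seen: same-number deviations correlated at -0.041, -0.036 and -0.126, and 0 of 3 control samples correlated best with its own number. With 3 arrays per group this cannot exclude that samples of equal number shared a culture or a processing run. Leaving out each sample gave 75 (control replicate 2) to 1217 (control replicate 3) probe sets, 48 to 773 genes, 28 (labelled Fosl1 replicate 1) to 169 (control replicate 3) genes of at least 2-fold and 2 (labelled Fosl1 replicate 3) to 6 (labelled Fosl1 replicate 1) lists. No result reversed among the named genes and lists that were called, and the 405 genes kept their direction in each setting that tested them, except 401 of 405 with the mean of a gene's probe sets. Cd55 and Prl3b1 were the 2 of the 405 genes called in all 15 settings with gene calls. Crb3 and Laptm5 were called in each of the 14 settings that tested them. The 60th percentile filter tested 381 of the 405 genes, and a gene left out there counts as not called. In every setting other than the fit without the trend, 31 of the 405 were called, counted the same way. Of 1070 comparisons of named genes in settings other than left-out samples, 903 kept their side of the threshold, 121 lost the call and 46 gained it. Dim signals limit the low-level genes such as Hsd11b2 and Mmp19.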

Other observations

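The 19 gene families below and the single genes named here were chosen after the data were seen, and nothing here was planned.

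Genes outside the fixed lists included several that stayed called whichever sample was left out. The small heat shock protein gene Hspb1 rose from 2686 ± 622 to 6163 ± 805 (SD, n = 3), 2.32-fold, with a limma adjusted p of 0.00329. Ptges, a prostaglandin E synthase, rose from 567 ± 74.2 to 1365 ± 257, and Bambi, a decoy receptor for TGF-beta family signals, from 310 ± 78.2 to 783 ± 98.7. Nptx1, a neuronal pentraxin, went from 3254 ± 1117 to 8695 ± 1540, and Mbnl3, a splicing regulator, from 5716 ± 181 to 11291 ± 312. Supt5h, an elongation factor of RNA polymerase II, fell from 5187 ± 246 to 2718 ± 133, with a limma adjusted p of 0.00111.

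Of 19 families defined by symbol, the zinc finger proteins had 111 of 175 members with lower values, with a median log2 difference of -0.11, a camera adjusted p of 0.0235 and an adjusted p = 0.548 with an estimated correlation. Limma called 2 of them lower and 1 higher, Zfp185. Of 11 serpins, Serpine2, Serpinb1a and Serpinh1 rose 2.05-, 2.06- and 1.80-fold, with a camera adjusted p of 0.0587 for the family, and Serpinh1 kept its call in 1 of the 6 runs without a sample. Of 191 solute carriers, 12 rose and 2 fell, with a camera adjusted p of 0.391. Ribosomal protein genes depended on the scaling: their median log2 difference was -0.03, with a camera adjusted p of 0.302 and an adjusted p = 0.824 with an estimated correlation, and -0.13 after quantile normalization, with a camera adjusted p of 1.56e-07 and an adjusted p = 0.363 with an estimated correlation.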
